A study of Homo sapiens with 9 samples.

How the data were processed

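The study measured gene expression by RNA sequencing in HUES8, an established human embryonic stem cell line, taken through definitive endoderm differentiation. Definitive endoderm is the embryonic layer that gives rise to the gut, liver and pancreas. Per the labels' protocols, the cells were grown on Matrigel and then received activin A at 100 ng/mL and Wnt-3a at 50 ng/mL with 0.2% albumin free of fatty acids for 2 days, after which Wnt-3a was withdrawn. Total RNA was extracted, per the labels. The 9 libraries form 3 groups of 3, named here as the labels name them. DE had no inhibitor, C75 received an inhibitor of fatty acid synthase, and ETO received an inhibitor of fatty acid oxidation. The labels give no dose, no start or length of the inhibitor treatment and no day of harvest. They do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

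The authors deposited 1 table of raw counts per gene symbol, with 1 column for each library and a gene length column. The gene lengths were those the authors gave, in bases. HISAT2 2.1.0 and featureCounts 1.6.4, and the human genome build GRCh38, are listed in the submitters' processing notes without a stated role. The annotation release, the strand setting of the counting, the treatment of reads that map to several places and the RNA selection are not given in the sources used here. The counts were whole numbers with different totals in each library. All 19907 symbols of the table matched GENCODE release 29 on GRCh38, and 19875 of them (99.84%) had a gene length equal to the summed length of their merged exons in that release. Positions and Ensembl identifiers are therefore given from GENCODE release 29. Because strand use is unknown, reads from exons that overlap on opposite strands may not be told apart. Overlap was counted here between whole gene spans, introns included, and overlap of exons was not computed. Of the 119 genes named by rule, 25 share part of their span with another gene of the table and 18 of these overlap a gene on the opposite strand, POU5F1 (with TCF19), CRELD2 (with ALG12), FGF2 (with NUDT6), PAX6 (with ELP4), SOX10 (with POLR2F), LGR5 (with TSPAN8), HSPD1 (with HSPE1), LOX (with SRFBP1) and TMOD1 (with TSTD2) among them. Values of LEFTY1 and LEFTY2, of HSPA1A, of POU5F1 and NANOG and of the metallothionein, histone and ribosomal protein genes are uncertain to the extent that reads were shared with near-identical copies or pseudogenes.

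From the deposited counts, differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 14177 genes holding 99.962% of all counts. Libraries were scaled by TMM factors, and quasi-likelihood F-tests (glmQLFit and glmQLFTest) were run in a single fit of all 9 libraries with group as the only term. The common biological coefficient of variation was 0.0335. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p below 0.05 were called. Standard errors (SE) of log2 fold changes were derived from the F statistics. Expression levels are CPM, a gene's counts scaled to a common library size with the TMM factors, given as the mean ± SD over the 3 libraries of a group.

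The 24 gene lists, the rule for naming genes, the tests and a set of alternatives were chosen before the data were examined. The lists covered markers of definitive endoderm, primitive streak and mesendoderm, pluripotency, mesoderm, ectoderm and neural tissue, trophoblast and amnion, and visceral endoderm, liver and gut. They also covered fatty acid synthesis, cholesterol synthesis and uptake, fatty acid oxidation, PPAR targets, glycolysis, the nuclear-encoded and the mitochondrial-encoded respiratory chain, the ATF4 integrated stress response, endoplasmic reticulum chaperones, the NRF2 antioxidant response, the cytosolic heat shock response, NODAL and activin targets, WNT targets, the cell cycle, p53 targets, epithelial-mesenchymal transition, and acetyl-CoA supply with protein acetylation. Lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 72 tests of 24 lists in 3 comparisons. Some genes stand in more than 1 list. The mean log2 CPM of each list per library, with a prior count of 2, was compared between groups with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

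The genes named are FASN and CPT1A, 10 stage markers (SOX17, FOXA2, CXCR4, GATA6, CER1, EOMES, TBXT, POU5F1, NANOG and SOX2), the 6 called genes with the largest rise and the 6 with the largest fall in each comparison, and up to 2 members of each list with the smallest p. The genes of largest change needed a mean of at least 5 CPM over the 9 libraries and no overlap between the libraries of the groups compared, and pseudogenes, unnamed transcripts, XIST and Y-linked genes were left out. A list with no called member was represented by its member of smallest p. Some genes that meet this rule are not reported here.

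Alternatives were DESeq2 median-of-ratios size factors and upper-quartile scaling in edgeR, no filter beyond 1 count, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0 with its own size factors, limma-voom, the replicate number as a block, a fit of only the 6 libraries compared, leaving out each of the 9 libraries, and a test against a log2 fold change of 0.5 (glmTreat). The correlation of fold changes was also computed over only the genes called in at least 1 comparison. Lists were also tested with an estimated inter-gene correlation and with fry. Removing the trend of each library with GC content and gene length through offsets was added after seeing the data. The trend fitted for a library included its mean level over genes, so this correction also rescaled the libraries. Effects of the trend and of the rescaling were not separated.

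The tests were checked on simulated counts in which 200 genes had been changed. For C75 versus DE, 56.7% of genes changed 1.2-fold, 79.1% of those changed 1.5-fold and 86.4% of those changed 2-fold were recovered, and 7 unchanged genes were called among 13817 tested. For ETO versus DE the shares were 49.3%, 77.6% and 92.4%, with 7 unchanged genes called among 13801. For C75 versus ETO they were 44.8%, 65.7% and 92.4%, with 8 unchanged genes called among 13785. Far fewer genes were changed there than the 63.1% to 79.2% called in these data. The shares recovered and the false calls may therefore not hold for these comparisons. Libraries of a group were also compared with each other. No pair had identical counts, and the chi-square per gene of the 9 pairs lay between 1.79 and 3.38, so each library was kept as a separate sample. Totals ran from 17379711 to 21510997 counts per library. Intervals given for genes with few counts cover counting error only.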

Results

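Expression was measured in HUES8 cells driven to definitive endoderm without inhibitor (DE), with C75, an inhibitor of fatty acid synthase, or with ETO, an inhibitor of fatty acid oxidation, in 3 libraries per group. The series asks how fatty acid synthesis and oxidation bear on this differentiation. Library totals ran from 17379711 to 20812616 counts in DE, from 18320778 to 18895819 in C75 and from 17743968 to 21510997 in ETO. Between 15948 and 16472 genes had at least 1 count in a library. The groups separated on the first principal component of log2 CPM, which held 79.7% of the variance and placed C75 at −64.3 ± 0.442, DE at −5.26 ± 1.38 and ETO at 69.5 ± 0.464. The second component held 10.7% and placed DE at −28.3 ± 1.14, apart from C75 at 15.8 ± 0.425 and ETO at 12.5 ± 0.266.

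FASN, which encodes fatty acid synthase, was expressed at 1496, 1465 and 1437 CPM in the DE libraries, at 1781, 1652 and 1808 CPM in the C75 libraries and at 1846, 1745 and 1869 CPM in the ETO libraries. FASN lies on chromosome 17 at 82078333 to 82098332 of GRCh38, on the minus strand (ENSG00000169710.8). Its transcript was higher than in DE with C75 (log2 fold change 0.25, SE 0.032, edgeR adjusted p = 2.1e-08) and with ETO (0.31, SE 0.032, adjusted p = 1.3e-10). C75 and ETO did not differ in FASN at the threshold (−0.06, SE 0.032, adjusted p = 0.088), but FASN was called lower in C75 without DE replicate 2, DE replicate 3, C75 replicate 1, C75 replicate 3 or ETO replicate 2, with log2 fold changes of −0.07, −0.07, −0.08, −0.10 and −0.09 and adjusted p of 0.033, 0.046, 0.047, 0.014 and 0.022. It was also called with median-of-ratios (−0.08) or upper-quartile scaling (−0.13), the stricter filter (−0.08), DESeq2 (−0.07), a fit of 6 libraries (−0.07) and the GC content and gene length correction (−0.06). CPT1A encodes the liver form of carnitine palmitoyltransferase 1, which admits long-chain fatty acids to mitochondrial oxidation, and lies on chromosome 11 at 68754620 to 68844410 (minus strand, ENSG00000110090.12). CPT1A was expressed at 37.0, 40.1 and 42.5 CPM in DE, at 24.2, 26.9 and 24.6 CPM in C75 and at 90.5, 86.0 and 92.6 CPM in ETO. It fell with C75 (−0.66, SE 0.062, adjusted p = 3.9e-11) and rose with ETO (1.17, SE 0.052, adjusted p = 3.2e-20). These are transcript levels and give no measure of enzyme activity.

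The first comparison asked what the fatty acid synthase inhibitor changed. In C75, several transcripts typical of definitive endoderm were higher than in DE and transcripts of the pluripotent state were lower. CXCR4, a chemokine receptor used to sort definitive endoderm, rose from 180 ± 1.90 to 633 ± 17.7 CPM (n = 3 each), 3.51-fold (adjusted p = 9.8e-31). GATA6 and CER1, an endoderm transcription factor and a secreted NODAL antagonist, rose 1.59-fold and 1.62-fold, and LHX1 rose 2.71-fold. The pluripotency factors POU5F1, NANOG and SOX2 were 4.78-fold, 2.81-fold and 6.79-fold lower, with POU5F1 at 61.6 ± 1.98 CPM against 295 ± 22.1 CPM in DE. TBXT, the brachyury gene of the primitive streak, was 5.33-fold lower at 1.42 ± 0.286 CPM against 7.60 ± 1.06 CPM. On GRCh38, SOX17 lies on chromosome 8 at 54457935 to 54460888, CXCR4 on chromosome 2 at 136114349 to 136118165, POU5F1 on chromosome 6 at 31164337 to 31180731 and LEFTY2 on chromosome 1 at 225936598 to 225941489. Smaller rises were measured for EOMES (log2 fold change 0.31, SE 0.029) and FOXA2 (0.28, SE 0.044). SOX17, a core endoderm transcription factor, was at 815 ± 43.5 CPM against 760 ± 23.7 CPM in DE (0.10, SE 0.034, adjusted p = 0.011), and this call was lost with upper-quartile scaling (0.05, adjusted p = 0.18), without DE replicate 3 (0.06, adjusted p = 0.18) and without C75 replicate 3 (0.04, adjusted p = 0.32).

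Of the 17 definitive endoderm markers measured, 13 rose and 2 fell in C75, and the list moved up as a whole (camera adjusted p = 9.8e-12). The pluripotency list moved down, with 13 of 17 members lower and 4 higher (adjusted p = 1.9e-13), SFRP2 among the lower ones at 6.11-fold. NODAL and activin targets moved up, with 9 of 12 higher and 2 lower (adjusted p = 2.3e-09). LEFTY2, a feedback inhibitor of NODAL, rose from 896 ± 27.0 to 2954 ± 36.1 CPM, and NODAL itself rose 1.87-fold. These 3 lists kept their calls with an estimated inter-gene correlation (adjusted p = 0.038, 0.038 and 0.018). Of the lists for other tissues none passed. Mesoderm markers had 1 higher and 4 lower of 12 (adjusted p = 0.059, and 0.049 without DE replicate 3), with the VEGF receptor gene KDR at a log2 fold change of −1.07 and FOXC1 1.73-fold lower. Trophoblast and amnion markers had 4 of 5 lower (adjusted p = 0.24), GATA3 and GABRP among them. GABRP was low and uneven, at 0.34, 0.72 and 1.70 CPM in the C75 libraries against 2.28, 1.71 and 1.80 CPM in DE. Ectoderm and neural markers had 4 higher, PAX6 among them, and 3 lower, NES among them, of 8 (adjusted p = 0.91). Visceral endoderm, liver and gut markers had 1 higher (APOA2) and 2 lower, TBX3 among them, of 8 (adjusted p = 0.91), and primitive streak markers had 6 higher, MIXL1 among them, and 3 lower of 11 (adjusted p = 0.32).

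Genes of lipid metabolism moved unevenly with C75. Of the 24 genes of cholesterol synthesis and uptake, 18 rose and the other 6 did not pass (camera adjusted p = 2.3e-05, with adjusted p = 0.064 under an estimated correlation). NSDHL, a sterol dehydrogenase, rose 1.90-fold. The fatty acid synthesis list had 10 of 18 higher and 5 lower (adjusted p = 0.068, and 0.039 without C75 replicate 2), and SREBF1, which encodes a transcription factor of lipogenic genes, rose 2.03-fold and the desaturase gene FADS2 1.48-fold. The fatty acid oxidation list had 11 of 26 higher and 8 lower (adjusted p = 0.28). ACADVL and ACSL1, encoding a long-chain acyl-CoA dehydrogenase and an acyl-CoA synthetase, rose 1.57-fold and 2.76-fold. PPAR targets had 1 higher and 2 lower of 6 (adjusted p = 0.94). The acetyl-CoA and acetylation list had 4 higher and 5 lower of 16 (adjusted p = 0.91), with ACLY 1.19-fold and CREBBP 1.26-fold higher.

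Most chaperone genes of the lists rose in C75. Endoplasmic reticulum chaperones had 13 of 16 higher and 1 lower (adjusted p = 2.7e-07), with CRELD2 at a log2 fold change of 0.97 and HSPA5 1.42-fold higher. The cytosolic heat shock list had 9 of 11 higher and 2 lower (adjusted p = 2.7e-07), with HSPA8 1.62-fold and DNAJA1 1.65-fold higher. Both lists kept their calls with an estimated correlation (adjusted p = 0.043 and 0.038). Of 21 cell cycle genes, 17 fell and the other 4 did not pass (camera adjusted p = 2.7e-04, adjusted p = 0.069 with an estimated correlation), and BUB1 and CENPF had log2 fold changes of −0.64 and −0.58. The p53 target list had 3 higher and 9 lower of 15 (adjusted p = 0.048), a call lost with an estimated correlation (adjusted p = 0.14) and with the replicate number as a block (adjusted p = 0.0503), with CDKN1A 3.69-fold lower and BBC3 at a log2 fold change of −1.07. The epithelial-mesenchymal transition list had 2 higher and 5 lower of 12 (adjusted p = 0.014, adjusted p = 0.13 with an estimated correlation), and its lower members included both CDH1, the epithelial cadherin, at 2.02-fold and VIM, a mesenchymal filament protein, at 1.51-fold. Of 13 mitochondrial-encoded genes, 11 rose and the other 2 did not pass (camera adjusted p = 0.0020, adjusted p = 0.45 with an estimated correlation), while mitochondrial transcripts took 3.42 ± 0.148% of counts against 3.01 ± 0.127% in DE. The nuclear-encoded respiratory chain had 4 higher and 6 lower of 25 (adjusted p = 0.61), UQCRC1 and NDUFV2 among the lower, and the call of NDUFV2 (−0.22) was lost with the GC content and gene length correction (−0.09, adjusted p = 0.085). Glycolysis had 6 higher and 11 lower of 22 (adjusted p = 0.13), with PKM 1.92-fold higher and PDK1 5.32-fold lower. The ATF4 list had 7 higher, SLC7A5 among them, and 12 lower, PHGDH among them, of 20 (adjusted p = 0.36). The NRF2 list had 8 higher, NQO1 and GCLM among them, and 3 lower of 14 (adjusted p = 0.11). WNT targets had 4 higher and 5 lower of 14 (adjusted p = 0.84), with DKK1 3.09-fold higher and DKK4 6.21-fold lower.

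Among the genes that rose most with C75 were FOXQ1, a forkhead transcription factor, at 178 ± 7.03 CPM against 13.4 ± 1.21 CPM (13.2-fold), MAMDC2 (9.04-fold), ABCG1, a cholesterol exporter (9.01-fold), NXPH4 (7.21-fold), the lysyl oxidase gene LOX (6.44-fold) and ADRA2A (5.14-fold). The genes that fell most left few counts in the 3 C75 libraries together, so their ratios are given with 95% counting intervals. GREM1, a BMP antagonist, had 2 counts in C75 against 251 in DE, a ratio of 118 (32.4 to 982). OLFML3 had 10 counts, 53.3-fold fewer (28.8 to 112). VAT1L was 48.7-fold lower (22.1 to 134), HPGD 32.6-fold (15.6 to 81.9) and HDAC9 32.2-fold (14.5 to 88.7).

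In all, edgeR called 4422 genes higher and 4524 lower in C75 than in DE, 63.1% of the 14177 genes tested. At least a 2-fold change was measured for 380 of the higher and 924 of the lower genes. Against a log2 fold change of 0.5, glmTreat called 690 higher and 1207 lower. With the GC content and gene length correction, which also rescaled the libraries, the split was 5609 higher and 3687 lower. With upper-quartile scaling it was 3757 higher and 5165 lower.

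**Figure D1:**
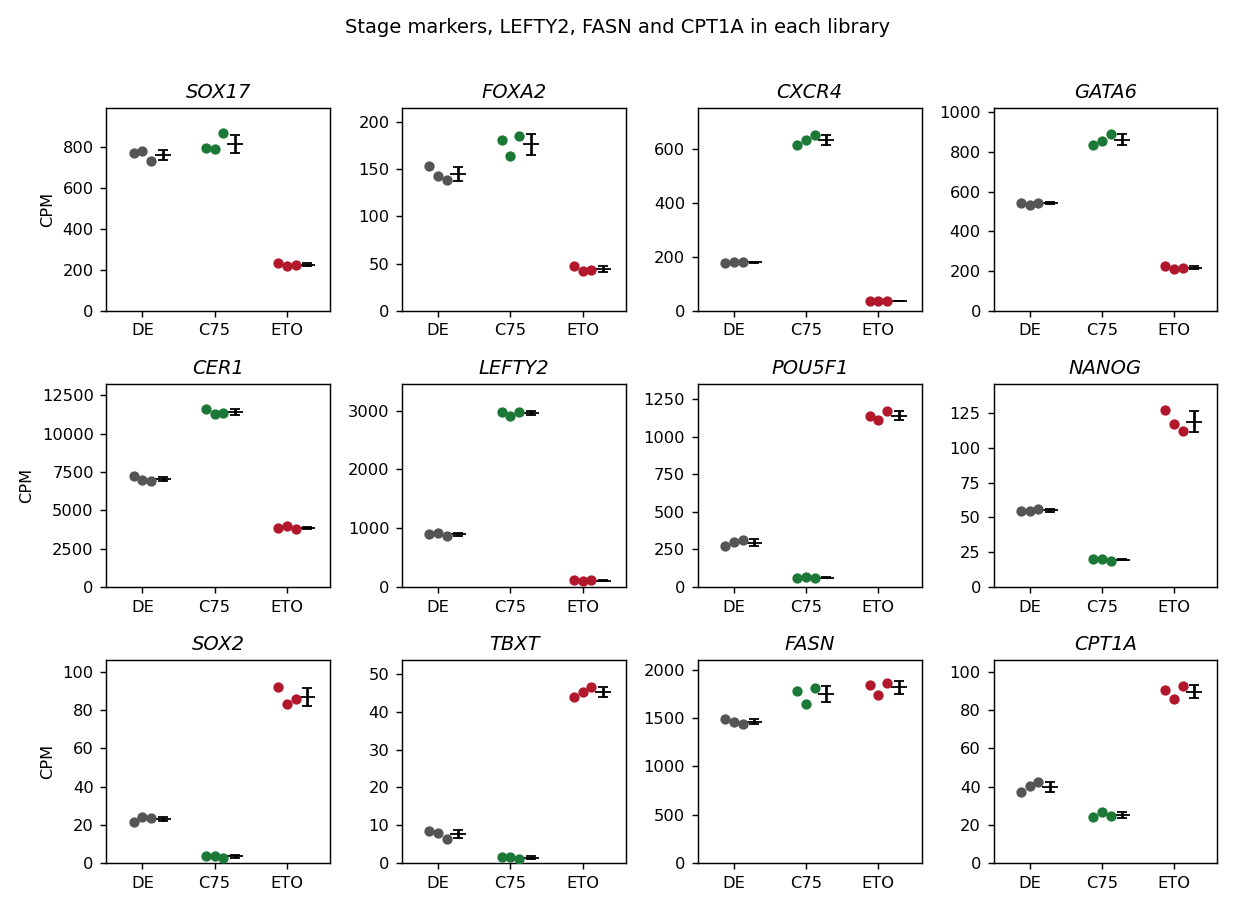
CPM (vertical axes, linear and starting at 0) of 12 genes in the 9 libraries. Points are single libraries and bars beside them the mean ± SD of the 3 libraries of a group. CXCR4, GATA6, CER1 and LEFTY2 were highest in C75 and lowest in ETO, and POU5F1, NANOG, SOX2, TBXT and CPT1A were highest in ETO and lowest in C75.

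The second comparison asked what the fatty acid oxidation inhibitor changed. In ETO, most definitive endoderm markers were lower than in DE, and most pluripotency markers and the streak gene TBXT were higher. SOX17 was at 226 ± 7.71 CPM against 760 ± 23.7 CPM in DE (n = 3 each), 3.36-fold lower (adjusted p = 7.8e-30), and FOXA2 was 3.28-fold lower. CXCR4 fell to 36.8 ± 1.26 CPM, 4.89-fold below DE. GATA6 and CER1 were 2.48-fold and 1.83-fold lower, and EOMES 1.16-fold lower, while LHX1 was higher (102 ± 4.29 against 66.7 ± 3.31 CPM), as in C75. POU5F1 rose to 1139 ± 29.3 CPM, 3.87-fold above DE (adjusted p = 1.3e-30). NANOG and SOX2 rose 2.16-fold and 3.79-fold, and TBXT rose 5.93-fold to 45.2 ± 1.26 CPM.

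Of the 17 definitive endoderm markers, 14 fell and 2 rose in ETO (camera adjusted p = 1.8e-24). NODAL and activin targets had 11 of 12 lower and 1 higher (adjusted p = 1.4e-13), with LEFTY2 8.27-fold lower at 108 ± 2.38 CPM and LEFTY1 5.95-fold lower. Both lists kept their calls with an estimated correlation (adjusted p = 0.018 and 0.0064). The pluripotency list had 12 of 17 higher and 5 lower (adjusted p = 5.8e-09, adjusted p = 0.064 with an estimated correlation), with FGF2 5.76-fold higher. WNT targets had 9 higher and 2 lower of 14 (adjusted p = 0.022, adjusted p = 0.15 with an estimated correlation), with DKK4 5.43-fold higher and the receptor gene LGR5 3.58-fold lower. Of lists for other tissues none passed. Mesoderm markers had 9 of 12 higher and 2 lower (adjusted p = 0.058, and 0.046 without ETO replicate 2), with KDR 2.85-fold and TWIST1 4.96-fold higher. Primitive streak markers had 6 higher and 4 lower of 11 (adjusted p = 0.62), FGF17 being 2.84-fold lower. Ectoderm and neural markers had 3 higher, NES among them, and 2 lower, SOX10 among them, of 8 (adjusted p = 0.93). Trophoblast and amnion markers had 2 higher, TFAP2C among them, and 2 lower of 5 (adjusted p = 0.91). Visceral endoderm, liver and gut markers had 2 higher and 4 lower of 8 (adjusted p = 0.19), with HNF4A 5.89-fold and APOA2 5.08-fold lower.

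Amino acid and stress genes of the ATF4 list rose in ETO, with 16 of 20 higher and 2 lower (adjusted p = 4.1e-09, adjusted p = 0.054 with an estimated correlation). ASNS, encoding asparagine synthetase, rose 3.60-fold and PSAT1, of serine synthesis, rose 3.16-fold. Of 21 cell cycle genes, 18 rose and the other 3 did not pass (camera adjusted p = 2.0e-06, adjusted p = 0.056 with an estimated correlation), CENPF and TOP2A among them at 1.93-fold and 1.72-fold. All 13 mitochondrial-encoded genes rose (adjusted p = 9.4e-08, adjusted p = 0.18 with an estimated correlation), with MT-ND6 1.77-fold and MT-ND5 1.71-fold higher, and mitochondrial transcripts took 4.36 ± 0.107% of counts against 3.01 ± 0.127% in DE. Glycolysis had 15 higher and 5 lower of 22 (adjusted p = 0.0058, adjusted p = 0.080 with an estimated correlation), with the glucose transporter gene SLC2A1 and the hexokinase gene HK1 at log2 fold changes of 1.38 and 1.17. The fatty acid oxidation list had 4 higher and 15 lower of 26 (adjusted p = 0.094), and EHHADH, a peroxisomal oxidation enzyme, was 6.68-fold lower. The fatty acid synthesis list had 10 higher, SCD and ACACA among them, and 6 lower of 18 (adjusted p = 0.28). Cholesterol synthesis had 15 higher, SC5D among them, and 7 lower, TM7SF2 among them, of 24 (adjusted p = 0.26). PPAR targets had 2 higher and 2 lower (ACADVL among them) of 6 (adjusted p = 0.75). The nuclear-encoded respiratory chain had 6 higher and 11 lower, UQCRC1 and SDHC among them, of 25 (adjusted p = 0.29), and the acetyl-CoA list 6 higher and 6 lower, PDHA1 and HDAC1 among them, of 16 (adjusted p = 0.89). Endoplasmic reticulum chaperones had 2 higher and 8 lower, CALR and MANF among them, of 16 (adjusted p = 0.22). The heat shock list had 6 higher, HSPD1 among them, and 4 lower, HSPA1A among them, of 11 (adjusted p = 0.75). The NRF2 list had 6 higher, SLC7A11 and TXNRD1 among them, and 4 lower of 14 (adjusted p = 0.28). The p53 list had 9 higher, RRM2B among them, and 3 lower, BTG2 among them, of 15 (adjusted p = 0.15). The epithelial-mesenchymal list had 7 higher and 3 lower of 12 (adjusted p = 0.22), with CDH1 2.11-fold higher and CDH2 1.71-fold lower.

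Among the genes that rose most with ETO were CREB5 (7.27-fold), VGLL3 (6.59-fold), the collagen gene COL12A1 (6.42-fold), GLIPR1 (6.39-fold) and VAT1L (6.32-fold, to 34.1 ± 1.12 CPM from 5.35 ± 0.826 CPM). The genes that fell most were RNASE1 (15.8-fold), NLRP9 (14.9-fold), ACSM4 (log2 fold change −3.32), CDH20 (8.68-fold), TMOD1 (8.66-fold) and LEFTY2. RNASE1, NLRP9 and CDH20 kept 43, 31 and 47 counts over the 3 ETO libraries. In all, edgeR called 4916 genes higher and 4999 lower in ETO than in DE, 69.9% of those tested, with at least a 2-fold change for 1356 and 680. Against a log2 fold change of 0.5, glmTreat called 1936 higher and 1308 lower. With the GC content and gene length correction, which also rescaled the libraries, the split was 4119 higher and 5863 lower. With upper-quartile scaling it was 5128 higher and 4731 lower.

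**Figure D2:**
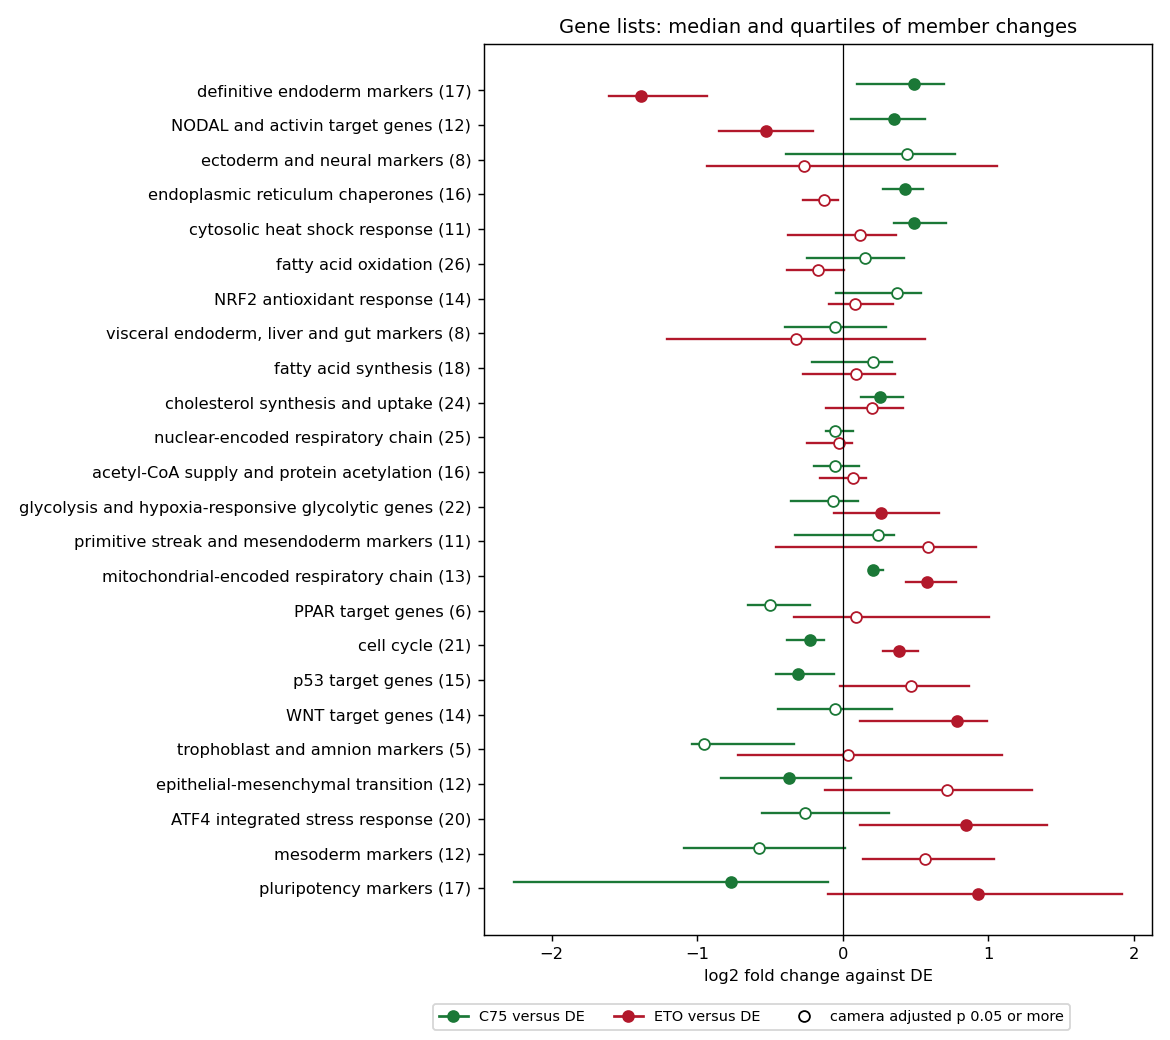
Median log2 fold change against DE (horizontal axis) of the measured members of 24 gene lists, with lines from the lower to the upper quartile, for C75 (green) and ETO (red). The number of measured members stands in brackets, and filled points mark lists with a camera adjusted p below 0.05. Definitive endoderm markers lay at 0.49 in C75 and −1.39 in ETO, and pluripotency markers at −0.77 and 0.93.

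The direct comparison of C75 with ETO tested the difference between the inhibitors. CXCR4 was 17.2-fold higher in C75 than in ETO, LEFTY2 27.3-fold and LEFTY1 8.57-fold, while POU5F1 was 18.5-fold lower, SOX2 25.7-fold, NANOG 6.07-fold and TBXT 31.6-fold lower. SOX17, FOXA2 and GATA6 were 3.61-fold, 3.99-fold and 3.95-fold higher in C75, CER1 was 2.96-fold and EOMES 1.44-fold higher, and CPT1A was 3.55-fold lower. Of the 17 definitive endoderm markers, 16 were higher and 1 lower in C75 (camera adjusted p = 2.8e-25), with OTX2 4.10-fold higher. Pluripotency markers had 4 higher and 13 lower of 17 (adjusted p = 2.2e-13), NODAL and activin targets 11 higher and 1 lower of 12 (adjusted p = 4.5e-15), and of 21 cell cycle genes 20 were lower and the other 1 did not pass (adjusted p = 1.1e-07). These 4 lists kept their calls with an estimated correlation (adjusted p = 0.018, 0.038, 0.0064 and 0.038). The ATF4 list had 6 higher and 12 lower of 20 (adjusted p = 8.4e-06, adjusted p = 0.090 with an estimated correlation), with ASNS 8.13-fold lower. Endoplasmic reticulum chaperones had 12 higher and 1 lower of 16 (adjusted p = 4.0e-04, adjusted p = 0.090 with an estimated correlation). Glycolysis had 5 higher and 14 lower of 22 (adjusted p = 0.0058, adjusted p = 0.064 with an estimated correlation), with PKM 2.86-fold higher and PDK1 8.52-fold lower. The heat shock list had 8 higher and 3 lower of 11, mesoderm markers 1 higher and 9 lower of 12, p53 targets 3 higher and 12 lower of 15, and the epithelial-mesenchymal list 3 higher and 7 lower of 12 (adjusted p = 0.040, 0.024, 0.040 and 0.040). Their adjusted p were 0.20, 0.11, 0.13 and 0.16 with an estimated correlation. The mitochondrial-encoded list had 1 higher and 10 lower of 13 (adjusted p = 0.057), and it passed without DE replicate 1 (0.044), DE replicate 2 (0.027), DE replicate 3 (0.044), C75 replicate 3 (0.029) or ETO replicate 3 (0.042), and with the replicate number as a block (0.039). The fatty acid oxidation list had 17 higher and 4 lower of 26 (adjusted p = 0.075), and fatty acid synthesis 7 higher and 8 lower of 18 (adjusted p = 0.93), with SREBF1 2.54-fold higher and ELOVL6 2.00-fold lower. The other lists did not pass. Among cell type markers, 4 primitive streak genes were higher and 6 lower of 11, 5 and 3 of 8 for ectoderm, 1 and 4 of 5 for trophoblast and amnion, and 5 and 3 of 8 for visceral endoderm (adjusted p = 0.91, 0.94, 0.50 and 0.42). Cholesterol synthesis had 12 higher and 7 lower of 24, PPAR targets 1 and 3 of 6, the nuclear-encoded respiratory chain 9 and 6 of 25, NRF2 8 and 3 of 14, WNT targets 4 and 10 of 14, and the acetyl-CoA list 6 and 6 of 16 (adjusted p = 0.28, 0.83, 0.76, 0.94, 0.21 and 0.89).

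The largest rises of C75 over ETO, besides LEFTY2, were PLCXD3 (25.3-fold), the receptor gene ERBB4 (24.0-fold, 851 ± 23.0 against 35.4 ± 2.28 CPM), ACSM4 (23.6-fold), TMOD1 (log2 fold change 4.40) and SOX21 (20.3-fold). Among the largest falls, the counting ratios were 733 for GREM1 (203 to 6057), 313 for OLFML3 (170 to 653), 308 for VAT1L (141 to 840), 195 for HDAC9 (89.4 to 533) and 191 for HPGD (92.5 to 476). In all, 5663 genes were higher and 5561 lower in C75 than in ETO, 79.2% of those tested, with at least a 2-fold change for 1253 and 2109. Against a log2 fold change of 0.5, glmTreat called 2475 higher and 3000 lower. With the GC content and gene length correction the split was 6976 higher and 4416 lower. The median log2 fold change of all genes was 0.17 against 0.01 without that correction. Calls between C75 and ETO are therefore relative to a median that this correction, which also rescaled the libraries, shifts. How much of the changed split came from the trends was not separated. With upper-quartile scaling the split was 5085 higher and 6089 lower. The corrected medians with the GC content and gene length trend removed were 0.07 in C75 versus DE and −0.08 in ETO versus DE.

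The responses to C75 and ETO were then compared gene by gene. Across the 14177 genes the log2 fold changes against DE had a Pearson r of −0.43 and a Spearman rho of −0.30. Genes are not independent replicates. Groups simulated without any change against the same DE libraries gave r = 0.50 ± 0.014 and rho = 0.45 ± 0.0084 (SD over 50 simulations). The covariance was −0.23 against 0.010 in the simulations, a difference of −0.24. Of genes called in both comparisons, 4561 moved in opposite directions and 2081 in the same direction, where independent lists would give 3128 and 3129, and 0 and 0.060 were called on average in the simulations without change. C75 raised and ETO lowered 2249 genes, CXCR4 and LEFTY2 among them, and C75 lowered and ETO raised 2312 genes, POU5F1 and SOX2 among them. Both inhibitors raised 955 genes, FASN and NXPH4 among them, and lowered 1126, UQCRC1 among them. The 3 DE libraries could not be split into parts of at least 2, so the shared controls remain in each of these values.

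**Figure D3:**
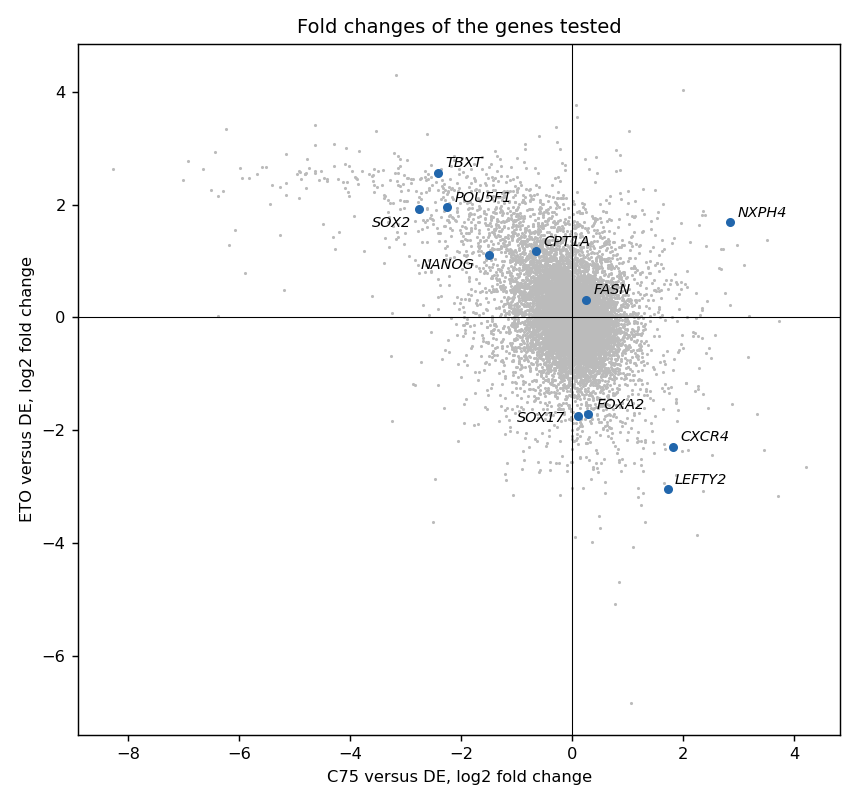
Log2 fold changes against DE with C75 (horizontal axis) and ETO (vertical axis) of the 14177 genes tested, 1 gray point per gene, with named genes in blue. SOX2, POU5F1 and TBXT lay in the upper left, CXCR4 and LEFTY2 in the lower right and NXPH4 in the upper right, and the Pearson r over all genes was −0.43.

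Counts of list members adjusted over the list alone were those given above for all lists and comparisons except 8. Adjusted over the list alone, C75 versus DE had 5 higher ectoderm genes, 6 lower fatty acid synthesis genes, 3 lower NODAL targets and 18 lower cell cycle genes, and ETO versus DE had 15 lower endoderm markers, 3 higher and 3 lower PPAR targets and 10 lower genes of the nuclear-encoded respiratory chain. C75 versus ETO had 21 lower cell cycle genes. The median, mean and test of a list differed in sign in C75 versus DE for primitive streak markers (median 0.25, mean −0.17, test up), ectoderm markers (0.44, −0.05, up), WNT targets (−0.05, −0.16, up) and the acetyl-CoA list (−0.05, −0.05, up). In ETO versus DE they differed for ectoderm markers (−0.26, −0.08, up) and the acetyl-CoA list (0.07, 0.13, down). They also differed in C75 versus ETO for primitive streak markers (−0.53, −0.58, up), visceral endoderm markers (0.30, −0.42, up), fatty acid synthesis (−0.0053, 0.021, up) and the acetyl-CoA list (0.0042, −0.17, up). The exact permutation test of list means per library reached its smallest possible p of 0.1 for 19 of 24 lists in C75 versus DE, 20 in ETO versus DE and 20 in C75 versus ETO.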

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

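The results below were picked out because the C75 and ETO effects against DE went in opposite directions. The single genes, taken from FASN, CPT1A and the stage markers, and the lists also had to pass in C75 versus ETO. That comparison is therefore no separate test of the difference here, and its values only give the size. Genes and lists chosen for opposite changes in the same fit are expected to differ between C75 and ETO. Groups of 3 libraries were not tested for outliers. The test against noise of the shared DE libraries and the correction for GC content and gene length were chosen only after the data were seen.

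Of the genes called in both comparisons with DE, 4561 had moved in opposite directions. Median log2 fold changes of C75 over ETO were 1.61 for definitive endoderm markers, −1.53 for pluripotency markers, 0.68 for NODAL and activin targets and −0.62 for the cell cycle list. Among single genes the C75 versus ETO log2 fold changes were 1.85 for SOX17, 2.00 for FOXA2, 4.10 for CXCR4, 1.98 for GATA6, 1.57 for CER1 and 0.53 for EOMES. They were −1.83 for CPT1A, −4.98 for TBXT, −4.21 for POU5F1, −2.60 for NANOG and −4.68 for SOX2.

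The share of doubly called genes in opposite directions was 68.7%, against 50.0% for independent lists. The GC content and gene length correction moved 58.4% of genes in C75 versus DE and 78.1% in ETO versus DE by over 0.05 in log2 fold change. Part of this was rescaling, since the medians of all genes moved from −0.005 to 0.07 and from −0.003 to −0.08. These shares therefore do not measure how much trend was removed. The share in opposite directions was then 69.7%, a value that rescaling can also move. The correlation of fold changes, which a shift common to all genes leaves alone, was −0.425 with the correction and −0.427 without it. That argues against those trends as the whole cause. Noise of the shared DE libraries gives a positive correlation (0.50 ± 0.014 in simulations), whereas r was −0.43. Opposite effects of the inhibitors on differentiation remain a candidate explanation, and so do different shares of cells in other states and any difference in how the groups were handled, since the labels separate the groups by treatment alone.

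Each comparison of 3 with 3 libraries has 10 splits of the 6 libraries, too few for a share under 0.05, of which 1, the real one, called as many genes. Fitted on the 6 libraries of a comparison alone, the real split called 8723 genes for C75 versus DE, 9853 for ETO versus DE and 11197 for C75 versus ETO. The highest of the other splits called 0 in each. Every other split mixes libraries of both groups, so a large group difference widens the spread within its parts. The 0 calls therefore add no evidence.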

How the results depend on the processing

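Of the alternatives, the GC content and gene length correction alone was chosen after seeing the data. All counts of genes stayed within 1.5 times their values except with glmTreat against a log2 fold change of 0.5, which called 690 higher and 1207 lower genes for C75 versus DE, 1936 and 1308 for ETO versus DE and 2475 and 3000 for C75 versus ETO, as a stricter test must. With each library left out, C75 versus DE had 3895 to 4462 higher and 4247 to 4546 lower genes, ETO versus DE 4704 to 4935 and 4571 to 5073, and C75 versus ETO 5427 to 5729 and 5409 to 5746. The correlation ran from −0.417 to −0.379 (−0.379 without DE replicate 1 and −0.391 without DE replicate 3, the cause was not tested), and opposite and same-direction overlaps ran from 4072 to 4400 and from 1840 to 2023. Every omission thus gave a weaker correlation than the −0.427 of the full set, and the stricter filter gave −0.453. The cause of these differences was not tested either. An estimated inter-gene correlation left 5, 2 and 4 lists passing in C75 versus DE, ETO versus DE and C75 versus ETO, against 10, 8 and 11, and fry, which does not compare a list with other genes, passed 18, 22 and 19; the cause of these shifts was not tested. With a library left out, 10 to 11, 8 to 9 and 11 to 12 lists passed. Deviations of same-numbered libraries correlated between −0.027 and 0.050 over all genes. Libraries of different number were not compared, so weak pairing by replicate number cannot be excluded. With the replicate block, 4429 and 4536 genes were called for C75 versus DE, 4923 and 5008 for ETO versus DE, and 5667 and 5563 for C75 versus ETO, r was −0.427, overlaps were 4567 and 2104, and 9, 8 and 12 lists passed. The p53 list in C75 versus DE was lost (adjusted p 0.0503) and the mitochondrial-encoded list in C75 versus ETO gained (0.039), and the block changed no other call of a list or named gene. Of 3762 values of named genes under alternatives 3718 kept direction and call, and none reversed. With glmTreat, 29 values of named genes lost their call. Of 936 list tests 878 kept their call, and no list called in both the main and the alternative test changed direction. The direction of other lists was not compared. Depth limits the folds of genes that C75 left with 10 or fewer counts, such as GREM1 with 2 (95% interval of the counting ratio of DE to C75 32.4 to 982). In simulations 44.8% to 56.7% of genes changed 1.2-fold were recovered.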

Other observations

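The gene families, the genes moved alike by both inhibitors and the tests of cell states and mitochondrial transcripts in this part were chosen only after the results were seen.

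The ID genes, inhibitors of basic helix-loop-helix factors that respond to BMP signalling, moved apart with the inhibitors. All 4 fell with C75, with ID1 at a log2 fold change of −1.41 (SE 0.054), and all 4 rose with ETO, ID4 by 1.18 (SE 0.12). Of 7 metallothioneins, which bind zinc and copper, 7 rose with ETO, MT2A by 2.16 (SE 0.12), and 4 fell with C75, MT1X among them with a log2 fold change of −3.02 (SE 0.24), while the other 3 did not pass. Cytosolic ribosomal protein genes had 73 of 82 lower with C75, with a median of −0.37, and 16 higher and 35 lower with ETO, with a median of −0.06. Histone genes had 14 of 22 higher with C75 and the rest did not pass, and had 4 higher and 3 lower with ETO. Families were matched by gene symbol, which can take in genes that are not true members. Genes with apolipoprotein symbols had 3 higher and 6 lower of 10 with ETO and 3 and 3 with C75. They include APOO, lower with both inhibitors, and APOOL, lower with C75 and higher with ETO, which are not true apolipoproteins. Of 5 keratins 1 was higher and 4 lower with ETO and 2 were higher with C75. Of 10 genes with S100 symbols 1 was higher and 7 lower with ETO and 7 were lower with C75. S100PBP, which encodes a binding protein and not an S100 protein, is among the 10 and among those lower with ETO (−0.38). Of 16 fibroblast growth factors 9 were higher and 3 lower with ETO and 3 higher and 10 lower with C75, and of 11 WNT ligands 8 were higher with ETO and 1 higher and 7 lower with C75. The remaining members did not pass. All 18 family medians had the same sign with median-of-ratios and upper-quartile scaling. No family passed with an estimated correlation (lowest adjusted p 0.081 over 18 tests), so each is a description.

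Some genes moved alike with both inhibitors. CTNNA2 fell from 14.3 ± 1.52 CPM in DE to 1.49 ± 0.239 CPM with C75 and 4.01 ± 0.0853 CPM with ETO (n = 3 each). The imprinted gene PEG10 fell from 1998 ± 80.6 CPM to 534 ± 3.12 and 734 ± 9.99 CPM, and MFAP4 from 399 ± 9.84 to 119 ± 6.10 and 158 ± 4.94 CPM. CCL2 and ANKRD1 were also lower with both. NXPH4 rose from 2.04 ± 0.279 CPM to 14.8 ± 0.951 and 6.64 ± 0.962 CPM, FAM43A from 4.45 ± 0.466 to 11.9 ± 0.638 and 14.5 ± 0.925 CPM, and DAB1 from 32.2 ± 0.890 to 71.4 ± 4.04 and 79.3 ± 2.49 CPM. They were taken from the genes whose smaller change of the 2 was largest.

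Genes that C75 lowered at least 16-fold shared nearly a single change in ETO. The 37 such genes with at least 30 counts in DE, GREM1, FGF4 and ANXA1 among them, had a median ETO log2 fold change of 2.46 (quartiles 2.29 and 2.63). Their robust SD was 1.41 times their median SE, as different shares of cells in another state could give. Of 10000 sets of other ETO-raised genes matched on expression, 1 was as narrow. Those sets drew genes independently, while the 37 were picked for a shared fall with C75. Genes regulated together could be as narrow, so this comparison does not separate cell shares from regulation within cells. The limit was set after other limits had been looked at, the ratio was between 0.79 and 1.75 for limits from −5 to −3 (at −3, 24 of 83 genes lay more than 3 SE from the median), and at the limit used 5 genes (TLE7, ALDH1A1, CXCL14, FSTL5 and ADGRD1) lay more than 3 SE from the median. Different shares of 1 such state would move every gene in opposite directions in C75 and ETO. Yet 917 of the 4422 genes higher in C75 (20.7%) had lower 95% limits above 0 in both comparisons without the TMM factors. The share was 3.06 ± 0.295% (SD over 50 simulations, highest 3.97%) where counts were simulated with DE libraries shared by both comparisons and ETO raised none of the genes that C75 raised. This argues against different shares as the whole cause of the C75 rises. The simulation held only the spread between libraries of a group, which may be technical. A deviation of the DE group as a whole, in culture or handling, would also give genes higher in both and was not simulated. Different shares of cells stay open for the 2249 genes that were higher in C75 and lower in ETO, as do changes within cells and more than 1 other state.

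Of 13 mitochondrial transcripts, 11 were called higher with C75 and 13 with ETO, though neither list call held with an estimated correlation (adjusted p = 0.45 and 0.18). A common factor for all 13 transcripts, as a uniform loss of other RNA would give, was argued against by a spread of 5.84 times their SE in ETO, where log2 fold changes ran from 0.19 to 0.83. Different shares of a single other cell state predict opposite signs in C75 and ETO, but the C75 median was 0.21 with 11 of 13 called higher. RNA quality, cell condition at harvest and a change in mitochondrial transcription may each remain, and none was tested.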
